A study of Arabidopsis thaliana with 16 samples.

How the data were processed

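Transcripts of shoots and roots of Arabidopsis thaliana were measured on Affymetrix ATH1 arrays in 8 groups of 2 arrays each. Per the labels' protocols, tissue was snap-frozen and ground, total RNA was extracted with a Qiagen plant kit, and biotin-labelled cRNA was made by the standard Affymetrix procedure, with the same wording for all 16 samples. The labels put 4 groups in a 7-week experiment (wild type, control or Zn-deficient medium, shoots or roots) and 4 in a 21-day experiment (wild type or hma2 hma4, shoots or roots). The groups, the main tests, the gene lists, the rule for named genes and all alternatives except 1 were fixed before the data were examined.

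The deposited table holds log2 values of signals, and per the submitters' processing notes the signals were computed with MAS5; its version and settings are not given in the sources used here. The values show that each array was scaled by the authors to a mean of 500 signal units after trimming 2% at either end. A log2 value of exactly 0 occurs 2413 times, which reads as signals set to 1. The deposited log2 values were taken back to linear signals, 8 units were added (the 10th percentile of all values), and log2 was taken again, so that every log2 change, and every fold not given as "at least", is on the log2(signal + 8) scale and understates the change of dim genes. Signals given as mean ± SD are linear signals over the 2 arrays of a group. No scanner files were used here, so probe-level steps were not examined, and a table already scaled to a common mean cannot show a change in total RNA.

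The 64 control probe sets were left out of the tests. Probe sets were kept where their mean signal over the arrays of the fit lay above the 25th percentile, which left 17059. Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Each experiment had 1 fit of 8 arrays, whose 4 groups shared 1 estimate of the spread, because a group of 2 arrays gives little information on its own. Differences between tissues were interaction terms of that fit. The difference between the response to Zn deficiency and that to the mutant used 1 fit of all 16 arrays, in which levels that differ between the experiments cancel. Called genes of both experiments, which share no arrays, were compared with Fisher's exact test among the probe sets tested in both.

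A probe set was taken as below background where no array of a group exceeded 52.2, the highest signal of 3 Trpn control probe sets over the 16 arrays. A fold against such a group is given as "at least" and is the ratio of the other group's geometric mean signal, without added units, to that level. The log2 change printed for such a gene depends on the 8 units added and is no bound.

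The platform annotation paired 13513 probe sets with 1 gene and 503 with several, and 8794 are not listed in it and stay unnamed here. Of the first, 13436 matched a gene of the RefSeq TAIR10.1 table, which was used for names and organelle membership only; the deposited table has no coordinates, and none are given. Probe sets with several genes are not named.

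There were 22 gene lists with 264 loci, of which 38 loci had a probe set of their own. In 8 lists no gene had one: nicotianamine synthesis, iron storage, carbonic anhydrases, salicylic acid, jasmonate, phosphate starvation, sulfate assimilation and cell division; these were not analysed here. Lists with at least 3 tested genes, namely iron deficiency, photosynthesis, root markers and plant defensins, were tested with camera from limma at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. Each gene entered with its probe set of highest mean signal.

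Named genes were chosen by rule: list members, the 8 named genes with the largest rise and the 8 with the largest fall among those past the threshold whose groups did not overlap and whose brighter mean exceeded the median of all values, the 4 largest each way for a difference between responses, and the genes called in both experiments. Some were named after their values were seen: the values of AT3G05170 in mutant shoots, of list members beyond those the rule picks (PDF2.1, PDF1.2B and PSAE1), of 1 unnamed probe set in the closing part, and of the families there. Families were formed from the letters that open a RefSeq symbol, with at least 6 tested members, plus the plastid-encoded genes and 1 range of receptor kinase genes on chromosome 1. Mitochondrion-encoded genes were recognised by matching symbols to the RefSeq records. Root-enriched and shoot-enriched probe sets had a mean signal above 1000 in their own tissue and below 60 in the other on the wild-type 21-day arrays.

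Each result was computed again with quantile normalization, median centring, an added constant of 1 or of 58 (the 30th percentile), no filter or a filter at the 50th percentile, eBayes without trend, the replicate number as a block, other sets of arrays in the fit, and each array left out in turn, where a lone array is assumed to vary like the other groups. The pipeline was tested on simulated data with 200 changed among 17059 probe sets in 20 draws. A log2 change of 1 was recovered for 9.48% of changed probe sets in Zn-deficient shoots, 8.36% in Zn-deficient roots, 65.9% in mutant shoots and 65.8% in mutant roots. A log2 change of 2 was recovered for 81.5%, 80.1%, 95.4% and 94.6%, in the same order. False calls made up 7.35%, 6.84%, 7.33% and 6.62% of calls, above the nominal 5%. The simulated noise was normal, independent between probe sets and equal in all groups of a probe set. These rates therefore need not hold where real groups differ in spread. They also rest on 200 changed probe sets. With fewer true changes the Benjamini-Hochberg method asks for a smaller unadjusted p, and recovery is lower. In the real data 18 probe sets were called in Zn-deficient roots and 1 in mutant roots, so recovery there may be far below these rates.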

Results

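Gene expression was measured on 16 one-colour Affymetrix ATH1 arrays, a microarray platform carrying 22810 probe sets for the transcripts of Arabidopsis thaliana. The arrays came from 2 experiments. In the first, wild-type plants were grown in hydroponic culture for 4 weeks and then kept for 3 more weeks in control medium or in zinc (Zn)-deficient medium, and shoots and roots were collected at 7 weeks. In the second, wild-type seedlings and seedlings of the hma2 hma4 double mutant were grown on agar with control medium, 7 days before and 14 days after transfer to fresh plates, and shoots and roots were collected at 21 days. HMA2 and HMA4 are metal pumps of the P-type ATPase family that load Zn into the xylem of the root for transport to the shoot, and plants without both pumps are known to move less Zn to the shoot. Each of the 8 groups had 2 arrays, and this number limits the precision of every value below. The labels do not say whether the replicates were separate plants or cultures, so the p-values measure the spread between these samples, which may be technical. The comparisons asked how shoots and roots responded to Zn deficiency, how they differed in the mutant, and whether both conditions changed the same genes.

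Array medians lay between 136.1 and 217 signal units after the scaling done by the authors. Signals of replicate arrays correlated across genes with r from 0.9403 to 0.9763 in the 7-week experiment and from 0.9709 to 0.9821 in the 21-day experiment. In the 7-week experiment r was 0.9505 in control and 0.9403 in Zn-deficient shoots, and 0.9763 and 0.9513 in roots. If shoots vary more than roots, the pooled spread makes the p-values in shoots too small. On Zn-deficient shoot replicate 1 the ratio of the 3' to the 5' actin probe set was 8.57, against 2.7, 2.36 and 1.74 on the other 3 shoot arrays of that experiment, and 243 signals stood at the lowest value, the most of the 16 arrays. The 25S ribosomal RNA control probe set had signals from 5387 to 6920 on the 4 wild-type arrays and from 1613 to 4240 on the 4 mutant arrays of the 21-day experiment. The median standard error of a log2 change was 0.322 in the 7-week experiment and 0.2 in the 21-day experiment. HMA2 and HMA4 were not analysed here, because no probe set is paired with either name in the annotation used, and the genotype labels were therefore not checked on the disrupted genes.

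In shoots of Zn-deficient plants, the largest rise among named genes was that of AT1G12030, whose signal was 2154 ± 563 (SD, n = 2) against 8.46 ± 4.5 in controls, at least 40.5-fold higher. ZIP9, which encodes a membrane protein of the ZIP family of Zn transporters, rose 32.3-fold, from 121.4 ± 17.9 to 4204 ± 978. AT1G20380, which encodes a peptidase of the prolyl oligopeptidase family, also rose 32.3-fold, from 190.5 ± 2.06 to 6526 ± 1810. UGT76B1, a glycosyltransferase that acts on salicylic acid and isoleucic acid, rose from 28.4 ± 36.4, near background, to 407.8 ± 4.73, and OSM34, which encodes an osmotin-like protein, rose 7.49-fold. The falls were smaller: the largest was that of AT5G22460, from 988.9 ± 343 to 160.7 ± 23.7.

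With limma, 157 of 17059 probe sets passed the adjusted threshold of 0.05 in Zn-deficient shoots, 131 higher and 26 lower, and all of them differed by at least 1 on the log2 scale. Of these, 67 were paired with 1 gene, 57 higher and 10 lower. AT1G12030 rose by 7.04 on the log2 scale (SE 0.330, limma adjusted p = 7.1e-05), AT1G20380 by 5.01 (SE 0.258, adjusted p = 7.8e-05) and ZIP9 by 5.01 (SE 0.285, adjusted p = 0.000123). The other large rises were those of AT2G44240 (4.56), UGT76B1 (4.02), AT5G12930 (3.34), the oxidoreductase gene AT1G26380 (2.95) and OSM34 (2.91), with limma adjusted p between 0.032 for OSM34 and 0.049 for AT1G26380. Both control signals of AT5G12930 (11.19 and 50.11) lay below background. So did control replicate 1 of AT2G44240 (11.42), UGT76B1 (2.641) and AT1G26380 (25.45). The sizes of these 4 rises therefore depend on the 8 units added. Among the genes that fell were AT5G22460 (log2 change -2.53), the thionin gene AT1G66100 (-2.20), AT5G26790 (-2.10), MSRB5, a methionine sulfoxide reductase (-1.88), and AT3G53980 (-1.73). RALFL24, a peptide of the RALF family, fell by 1.61, AT2G43535 by 1.43 and AT2G43550 by 1.37, with limma adjusted p of 0.0415, 0.039 and 0.0444.

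Of the list of Zn deficiency core genes, the targets of the transcription factors bZIP19 and bZIP23, ZIP9 was the only member with a named probe set, and it rose. ZIP6, of the ZIP family outside that core, had a log2 change of -0.13 and did not pass. On the Zn export and sequestration list, neither MTP2 nor MTP12 passed in shoots over all probe sets tested, and 1 gene, MTP2, rose when adjusted over the list alone. MTP2, a member of the cation diffusion facilitator family, had a signal of 72.5 ± 17.2 against 19.4 in controls, a log2 change of 1.55 (limma adjusted p = 0.0819), and MTP12 a log2 change of 0.12. The photosynthesis list had 8 tested members, of which 0 passed over all probe sets and 0 when adjusted over the list alone, yet all 8 had negative changes with a median of -0.33. Under other settings or with 1 array left out, that median lay between -0.515 and -0.0905. This list was called by camera (adjusted p = 0.0389) and not with an estimated correlation (adjusted p = 0.235). Its members included SBPASE (-0.89) and PRK (-0.66), enzymes of the Calvin cycle, and RCA (-0.34), the rubisco activase.

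The iron deficiency list had 0 of 5 tested members past the threshold in Zn-deficient shoots and 1, F6'H1, when adjusted over the list alone (camera adjusted p = 0.801). F6'H1, the enzyme that opens coumarin synthesis, had a signal of 2275 ± 385 against 147.1 ± 185 in controls, a log2 change of 4.77 (SE 0.885, limma adjusted p = 0.0521) that was 2.99 without control replicate 1 and 6.56 without control replicate 2, both past the threshold. The plant defensin list had 0 of 6 members past the threshold, 1 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.801). The list of 3 root marker genes had a camera adjusted p of 0.99. On the flavonoid and anthocyanin list, DFR (-1.38) and UF3GT (-1.40) did not pass over all probe sets and both were lower when adjusted over the list alone. Their Zn-deficient arrays lay apart, with signals of 966.9 ± 717 for DFR and 773.9 ± 465 for UF3GT, and the log2 changes were -2.21 and -2.04 without Zn-deficient replicate 1, the array with the high actin ratio, and -0.55 and -0.75 without Zn-deficient replicate 2. CCS, the copper chaperone of superoxide dismutase, had a log2 change of -1.87 that did not pass and rested on 1 control array, with a control signal of 1481 ± 1710: it was -0.22 without control replicate 1, and -3.51 and past the threshold without control replicate 2. GI, a clock gene and the only tested member of its list, had a log2 change of 1.17 and did not pass. Its limma unadjusted p lay under 0.05, as for 2849 of the 17059 probe sets. The change of GI was 0.57 without control replicate 1 and 1.78 without control replicate 2. CITF1 of the copper deficiency list, HSP22 of the heat shock list, MT1C of the metallothionein list and the reference genes SAND and TIP41 had log2 changes of 0.17, -0.48, -0.21, 0.17 and 0.27, and did not pass.

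The calls of AT1G12030, AT1G20380 and ZIP9 in Zn-deficient shoots held with each of the 4 shoot arrays left out in turn, whereas the count of 157 became 17 without control replicate 1, 331 without control replicate 2, 41 without Zn-deficient replicate 1 and 66 without Zn-deficient replicate 2. AT2G44240, UGT76B1, AT5G12930, AT1G26380 and OSM34 each kept their call without control replicate 2 and lost it when any 1 of the other 3 shoot arrays was left out. Their size depended on the control arrays: without control replicate 1 and 2 the log2 change was 3.36 and 5.75 for AT2G44240, 2.74 and 5.29 for UGT76B1, 2.54 and 4.14 for AT5G12930, 2.23 and 3.66 for AT1G26380, and 2.19 and 3.62 for OSM34. The 8 named genes that fell kept theirs in 0 to 2 of these 4 fits.

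**Figure D1:**
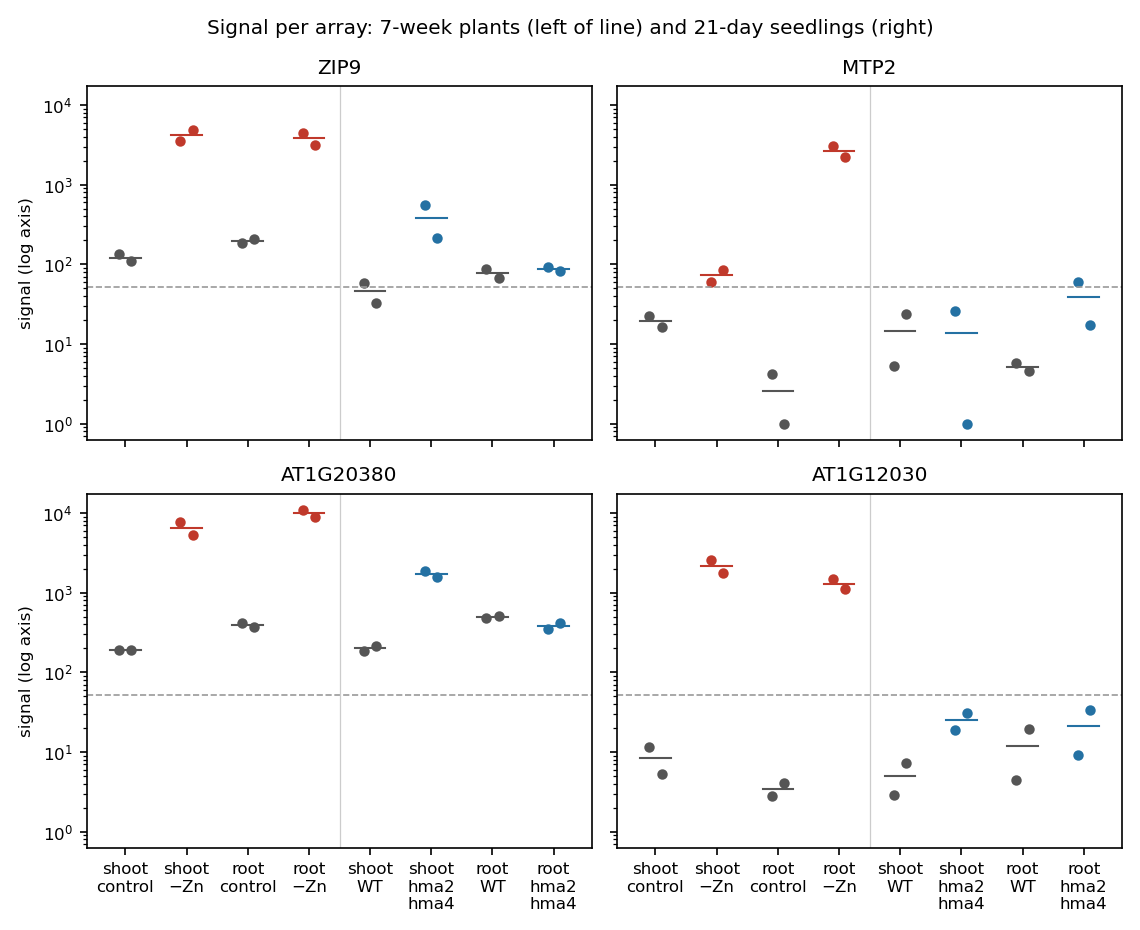
Signal of ZIP9, MTP2, AT1G20380 and AT1G12030 on each of the 16 arrays, on a log axis, by tissue and by condition or genotype. Points are arrays, short horizontal lines are means of 2 arrays, red marks Zn deficiency and blue the hma2 hma4 mutant, and the dashed line is the background level of 52.2. ZIP9 and AT1G20380 were high in Zn-deficient shoots and roots and in mutant shoots, and were not called in mutant roots.

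In roots of Zn-deficient plants, a small group of genes rose strongly and 0 genes fell past the threshold. MTP2 had a signal of 2658 ± 623 (SD, n = 2) against 2.586 ± 2.24 in controls, at least 50.2-fold higher. AT1G12030 was at least 24.2-fold higher, at 1280 ± 262 against a control signal below background. AT1G20380 rose 24.5-fold, to 9922 ± 1350, and ZIP9 rose 18.5-fold, from 196.3 ± 13.4 to 3823 ± 973.

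With limma, 18 of 17059 probe sets passed in Zn-deficient roots, all higher and all by at least 1 on the log2 scale, and 394 had an unadjusted p under 0.05, 137 of them lower. MTP2 rose by 7.97 on the log2 scale (SE 0.352, limma adjusted p = 6.35e-05), AT1G12030 by 6.80 (SE 0.330, adjusted p = 6.35e-05), AT1G20380 by 4.61 (SE 0.258, adjusted p = 0.00016) and ZIP9 by 4.21 (SE 0.285, adjusted p = 0.00048). These 4 were the named genes among the 18, and 14 probe sets had no single gene name. Of the 18 probe sets, 14 were also among the 131 that rose in shoots, against 0.138 for independent lists (Fisher's exact test, two-sided p = 3.62e-27). Both tissues share 1 estimate of the spread per probe set, so the lists are not fully independent and this p-value is a description. The interaction of Zn deficiency and tissue passed for 2 probe sets with limma, with 1514 at an unadjusted p under 0.05. One was MTP2, whose log2 change was larger in roots by 6.43 (SE 0.498, adjusted p = 0.00486), and the other was an unnamed probe set.

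ZIP9 of the Zn deficiency core list and MTP2 of the Zn export and sequestration list rose in Zn-deficient roots, and MTP12 of the latter list did not pass. The iron deficiency list had 0 of 5 members past the threshold, also when adjusted over the list alone (camera adjusted p = 0.81). F6'H1 was high in both root groups, at 7937 ± 1040 in Zn-deficient and 9409 in control roots, a log2 change of -0.25. The plant defensin list was called by camera (adjusted p = 0.0478), with 5 of 6 members negative and a median of -0.33, and not with an estimated correlation (adjusted p = 0.396); 0 members passed, also when adjusted over the list alone. The most abundant members were PDF2.2 (-0.31) and PDF2.3 (-0.47), small cysteine-rich proteins. The photosynthesis and root marker lists had camera adjusted p of 0.166 and 0.324. MTP12, ZIP6, CCS, CITF1, HSP22, MT1C, DFR, UF3GT, GI, SAND and TIP41 had log2 changes of -0.26, -0.08, -1.88, 0.09, -0.09, -0.30, -0.33, 0.10, 0.04, 0.03 and -0.07, and did not pass. The change of CCS in roots was -1.16 without Zn-deficient replicate 2 and -2.60 without Zn-deficient replicate 1.

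MTP2, AT1G12030, AT1G20380 and ZIP9 kept their root calls with each of the 4 root arrays left out, and the count was 29 without Zn-deficient replicate 2 and 12 without Zn-deficient replicate 1. The MTP2 interaction passed in 5 of 8 fits with 1 array left out, and the count of 2 became 0 without either Zn-deficient shoot array, 16 without control shoot replicate 2 and 4 without Zn-deficient root replicate 2.

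In shoots of the hma2 hma4 mutant, AT1G20380 was 8.39-fold higher than in the wild type, at 1737 ± 217 (SD, n = 2) against 199.6 ± 18.3, and ZIP9 was 6.77-fold higher, at 383.1 ± 242 against 45.6 ± 18.4. The size for ZIP9 is uncertain: under other settings or with 1 array left out, its log2 change lay between 1.984 and 3.435. XTH33, an enzyme that remodels cell wall xyloglucan, rose 5.56-fold, and AT5G27920, an F-box protein gene, rose 3.21-fold with little scatter. STZ, a zinc-finger transcription factor of stress responses, fell from 685 ± 57.4 to 278.2 ± 28.6.

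With limma, 51 of 17059 probe sets passed in mutant shoots, 32 higher and 19 lower, of which 23 and 15 differed by at least 1 on the log2 scale. Of the 51, 26 were paired with 1 gene, 18 higher and 8 lower. AT1G20380 rose by 3.07 on the log2 scale (SE 0.159, limma adjusted p = 1.03e-05), ZIP9 by 2.76 (SE 0.425, adjusted p = 0.0313), XTH33 by 2.48 (SE 0.369, adjusted p = 0.0293) and AT5G27920 by 1.68 (SE 0.132, adjusted p = 0.000291). The aspartyl protease gene AT4G16563 rose by 2.23, AT4G32800, of the AP2/ERF transcription factors, by 1.91, AT2G30930 by 1.14 and TBL38 by 1.14. STZ fell by 1.28 (SE 0.195, limma adjusted p = 0.0313) and AT1G04770 fell by 1.18 (SE 0.157, adjusted p = 0.0146).

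The photosynthesis, root marker and defensin lists each had a camera adjusted p of 0.842 in mutant shoots. The iron deficiency list had 0 of 6 members past the threshold, also when adjusted over the list alone, and all 6 were negative with a median of -0.29 (camera adjusted p = 0.104). On the defensin list 0 of 5 members passed and 1, PDF2.1 (0.61), was higher when adjusted over the list alone. CCS (0.71) and GI (-0.52), each the only tested member of its list, did not pass. Their limma unadjusted p lay under 0.05, as for 1638 of the 17059 probe sets, and the change of CCS was 0.88 without mutant replicate 1. ZIP6, MTP12, MT1C, DFR, UF3GT, SAND and TIP41 had log2 changes of -0.23, 0.40, -0.04, -0.01, -0.18, -0.03 and 0.09, and did not pass; MTP2, CITF1 and HSP22 were below the signal filter in this experiment.

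AT1G20380 and AT5G27920 kept their calls in mutant shoots with each of the 4 shoot arrays left out, ZIP9 kept its call in 1 of these 4 fits, AT2G30930 in 3, and XTH33, AT4G16563, AT4G32800, TBL38, STZ and AT1G04770 in 2 each. The count of 51 became 15 without wild-type replicate 1, 152 without mutant replicate 1 and 179 without mutant replicate 2.

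In roots of the hma2 hma4 mutant, AT3G05170, of the phosphoglycerate mutase family, was the only gene past the threshold, at 272.1 ± 60.7 (SD, n = 2) against 12.67 ± 4.09 in the wild type, at least 5.14-fold higher. Among wild-type arrays it was below background only in the 21-day experiment. Its signals in 7-week control roots were 145.9 and 173.1, and the source of this difference was not tested. Of the genes that rose in Zn-deficient roots, ZIP9 had a signal of 87.9 ± 8.29 against 77.0 ± 13.5, and AT1G20380 a signal of 380.4 ± 48.5 against a wild-type mean of 494.8. MTP2 had a signal of 38.4 ± 30.1 against 5.20 and lay below the signal filter of this experiment. Only mutant replicate 1 (59.66) exceeded background, so the higher value of mutant replicate 2 (17.16) is a difference within background.

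AT3G05170 rose by 3.76 on the log2 scale in mutant roots (SE 0.384, limma adjusted p = 0.0197), and it also rose in mutant shoots, by 2.56 (SE 0.384, adjusted p = 0.0293). With limma, 629 probe sets had an unadjusted p under 0.05 in mutant roots, 311 higher and 318 lower. ZIP9 had a log2 change of 0.18 and AT1G20380 of -0.38 in mutant roots, and neither passed. The interaction of genotype and tissue passed for 8 probe sets, all with a lower change in roots than in shoots, with 1027 at an unadjusted p under 0.05. The 3 named ones were AT1G20380 (-3.45, SE 0.225, limma adjusted p = 0.000111), AT2G19970, of the CAP protein family (-2.65, SE 0.305, adjusted p = 0.0103), and AT5G27920 (-1.36, SE 0.186, adjusted p = 0.0395). The size for AT2G19970 depends on the added constant, since its wild-type shoot signal of 8.167 ± 1.37 lay below background and its mutant shoot signal of 70.7 ± 5.08 was at least 1.35-fold higher. AT1G20380 kept this call in 8 of 8 fits with 1 array left out. AT2G19970 kept it in 6, not without wild-type root replicate 1 or mutant root replicate 2, and under 6 of 9 other settings. AT5G27920 kept it in 2, only those without mutant shoot replicate 1 or 2, and under 4 of 9 other settings. For ZIP9 the interaction was -2.58 and did not pass (limma adjusted p = 0.326).

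The photosynthesis list was called by camera in mutant roots (adjusted p = 0.0266), with 7 of 8 members negative and a median of -0.15, and not with an estimated correlation (adjusted p = 0.566); 0 members passed, also when adjusted over the list alone. Signals of this list were low in roots, with PSAE1 at 404.3 against 516.1 and RCA at 328.3 against 335.9. The iron deficiency, root marker and defensin lists had camera adjusted p of 0.568, 0.548 and 0.122, and 1 defensin, PDF1.2B (-0.88), with signals below background in both groups, was lower when adjusted over the list alone. GI, the only tested member of its list, had a log2 change of -0.55 and did not pass. Its limma unadjusted p lay under 0.05, as for 629 of the 17059 probe sets. ZIP6, MTP12, CCS, MT1C, DFR, UF3GT, SAND and TIP41 had log2 changes of -0.19, -0.00436, 0.09, 0.28, -0.03, -0.02, -0.09 and -0.04, and did not pass. Without mutant replicate 1 the count in mutant roots was 0, without wild-type replicate 2 it was 6, and AT3G05170 kept its call in 1 of these 4 fits, as the single call without wild-type replicate 1 or mutant replicate 2 was of another probe set; the count of 8 for the interaction was 18 and 28 without mutant shoot replicate 1 and 2.

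**Figure D2:**
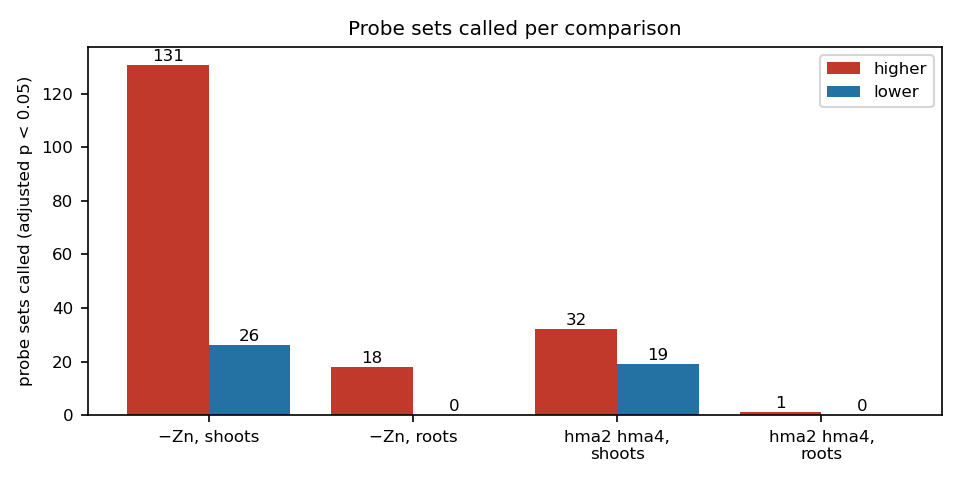
Number of probe sets with a limma adjusted p under 0.05 in each comparison, higher in red and lower in blue, on an axis that starts at 0. Zn deficiency gave 131 higher and 26 lower in shoots and 18 higher and 0 lower in roots; the mutant gave 32 and 19 in shoots and 1 and 0 in roots.

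The genes called in Zn deficiency and in the mutant overlapped in shoots, and no overlap was called in roots. ZIP9 and AT1G20380, together with 4 unnamed probe sets, rose in both shoot comparisons. All 6 of these also rose in Zn-deficient roots, and none of them passed in mutant roots. In mutant shoots their log2 changes lay between 2.76 and 3.88, against 4.03 to 6.06 in Zn-deficient shoots.

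Of the 16202 probe sets tested in both experiments, 121 rose in Zn-deficient shoots and 32 in mutant shoots, and the 6 in common compare with 0.239 for independent lists (Fisher's exact test, two-sided p = 1.18e-07). For the other directions in shoots, the overlap was 0. In roots, 15 probe sets rose in Zn deficiency and 1 in the mutant, with an overlap of 0 against 0.000926 for independent lists (Fisher's exact test, two-sided p = 1), counts too small to show a difference from chance. The log2 changes of both comparisons correlated across genes with a Pearson r of 0.0771 (Spearman 0.094) in shoots and 0.00279 (Spearman 0.0301) in roots; genes are not independent replicates.

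The difference between both responses was tested directly over all 16 arrays with limma. In roots 21 probe sets passed, 19 of them with the higher change in Zn deficiency, and 396 had an unadjusted p under 0.05. AT1G20380 differed by 4.99 (SE 0.297, limma adjusted p = 2.03e-06), AT1G12030 by 6.27 (SE 0.716, adjusted p = 0.00114), MTP2 by 6.33 (SE 0.923, adjusted p = 0.0106) and ZIP9 by 4.03 (SE 0.536, adjusted p = 0.00539). AT3G05170 differed the other way, by -3.48 (SE 0.419, limma adjusted p = 0.00188). In shoots 99 probe sets passed, 68 with the higher and 31 with the lower change in Zn deficiency. Among them AT1G12030 differed by 5.71, F6'H1 by 5.06, UGT76B1 by 4.40 and AT4G39670 by 3.34, and AT4G35320 by -3, AT5G25240 by -2.85, AT3G26700 by -1.96 and AT2G18890 by -1.88, with limma adjusted p from 0.00431 for AT1G12030 to 0.0495 for F6'H1.

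The experiments differed in plant age, in culture and in the signals of their control probe sets, so the difference between both responses cannot be told apart from a difference between experiments. The count of 99 in shoots was 776, 524 and 775 without control shoot replicate 2, Zn-deficient shoot replicate 1 and 2, and 15, 28, 35 and 38 without wild-type shoot replicate 1, 2 and mutant shoot replicate 1, 2. In shoots AT1G12030 kept its call in 8 of 8 fits with 1 array left out, AT4G35320 in 6, UGT76B1 in 5, F6'H1 in 4, and AT5G25240, AT4G39670, AT3G26700 and AT2G18890 in 3 each; F6'H1 kept it under 3 of 8 other settings. In roots AT1G20380, AT1G12030 and AT3G05170 kept theirs in 8 of 8 and ZIP9 in 7, not without wild-type root replicate 1. MTP2 kept its root call in 4 of 8, not without control root replicate 2, Zn-deficient root replicate 1, wild-type root replicate 1 or mutant root replicate 2, and under 6 of 8 other settings. The count of 21 in roots was 11 without wild-type root replicate 1 and 50 without Zn-deficient root replicate 2.

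**Figure D3:**
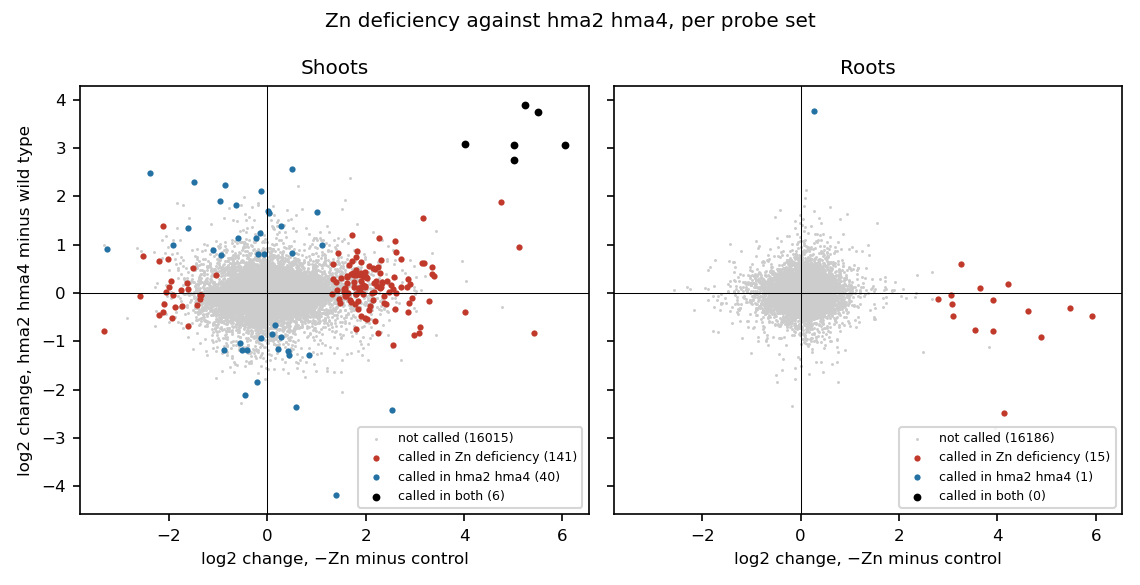
Log2 change in Zn deficiency (horizontal axis) against log2 change in the hma2 hma4 mutant (vertical axis) for the 16202 probe sets tested in both, in shoots and in roots. Each point is a probe set; grey was not called, red was called in Zn deficiency, blue in the mutant and black in both. The 6 black points of the shoot panel lie at the upper right, and the root panel has none.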

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

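The tests of differences between responses were planned, whereas all tests of an explanation in this part were chosen after the result was seen, and those for mutant roots replaced an earlier form. Each value was singled out either because a test found a response to differ between tissues or experiments, or because a control probe set outside the comparisons had a higher signal on every array of 1 experiment than on any of the other.

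Genes raised in Zn-deficient roots were not called in mutant roots. MTP2 had a higher signal on both mutant arrays (log2 change 1.65, upper 95% bound 3.29). Of these root arrays only mutant replicate 1 lay above background, so this change and its bound depend on the added constant. In roots 21 probe sets differed between both responses, among them AT1G20380 (4.99), AT1G12030 (6.27), MTP2 (6.33, a call kept in 4 of 8 fits with 1 array left out) and ZIP9 (4.03), and 15 of the 18 probe sets called in Zn-deficient roots were among the 21. The overlap of 15 is not independent evidence, because the 18 were called on Zn-deficient and control root arrays that also enter the difference. Low sensitivity of the mutant root arrays is argued against only for a rise as large as that measured in Zn deficiency. For 18 of these 18 the upper 95% bound in mutant roots lay below the change measured in Zn-deficient roots. Those changes belong to probe sets selected for passing there and entered without their own error, so they may be overstated. A smaller rise stays open for those with a bound above 0. For 4 of the 6 probe sets called in both shoot comparisons the bound lay below 0. Exchanged genotype labels among the root arrays are argued against too: of the 45 other probe sets called in mutant shoots, 32 had the same sign in mutant roots (exact binomial test, two-sided p = 0.00661, which takes genes as independent), and so did all 6 of them with a limma unadjusted p under 0.05. A candidate explanation is that mutant roots, which lack both export pumps, were not short of Zn on this medium, but Zn was not measured here, and plant age and culture differ between the experiments and stay open, as untested.

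F6'H1, the gene that opens coumarin synthesis, differed between both responses in shoots by 5.06 (limma adjusted p = 0.0495; the call held under 3 of 8 other settings and in 4 of 8 fits with 1 array left out, with a highest adjusted p of 0.2 over these), from a signal of 2275 ± 385 (SD, n = 2) in Zn-deficient shoots. Root RNA in the Zn-deficient shoot samples is argued against, because F6'H1 reached 2275 against 7937 in Zn-deficient roots, while the median of 78 root-enriched probe sets was at most 24.2 on those arrays, against 1010 to 1230 in roots. A single array is argued against as the source of the whole rise, but its size and call depend on single arrays: the log2 change was 2.99 and 6.56 without control replicate 1 and 2 (limma adjusted p = 0.00851 and 0.000366), and 4.94 and 4.60 without Zn-deficient replicate 1 and 2 (limma adjusted p = 0.116 and 0.105). A change of F6'H1 with Zn supply in shoots is a hypothesis, and the scatter of the controls (147.1 ± 185) limits it, as the change within the Zn experiment missed the threshold (limma adjusted p = 0.0521).

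The remaining differences between responses are given as values. In shoots 99 probe sets differed between Zn deficiency and the mutant. Of these, AT1G12030 (5.71), UGT76B1 (4.40) and AT4G39670 (3.34) had the higher change in Zn deficiency. AT4G35320 (-3), AT5G25240 (-2.85), AT3G26700 (-1.96) and AT2G18890 (-1.88) had the lower change. In roots AT3G05170 differed by -3.48, and it rose in mutant roots and shoots. Between tissues, 2 probe sets differed in their response to Zn deficiency, MTP2 among them (6.43). For the mutant, 8 differed, including AT1G20380 (-3.45), AT2G19970 (-2.65, with a wild-type shoot signal below background) and AT5G27920 (-1.36, a call kept in 2 of 8 fits with 1 array left out).

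Control probe sets outside the comparisons separated the experiments. The bacterial control transcripts dap, lys, phe and thr had lowest signals of 7675, 1645, 3143 and 6659 on the 21-day arrays and highest signals of 13, 40.46, 56.22 and 26.96 on the 7-week arrays. The 25S ribosomal RNA probe set had a lowest signal of 1613 on the 21-day arrays, against a highest of 449.9 on the 7-week arrays. It also separated the genotypes of the 21-day experiment, with 5387 or more on the 4 wild-type arrays and 4240 or less on the 4 mutant arrays, and its relation to the calls in the mutant was not tested. The ratio of the 3' to the 5' actin probe set lay between 17.3 and 30.3 on the 21-day arrays and between 1.74 and 8.57 on the 7-week arrays, where the 8.57 is that of Zn-deficient shoot replicate 1, without which 41 probe sets were called in Zn-deficient shoots in place of 157. Apart from the wild-type signals of AT3G05170, levels were not compared between experiments.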

How the results depend on the processing

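Of the settings in this part, 1 was chosen after the data were seen: a crossed block for Zn deficiency in roots. No called result reversed its direction under any setting. Where a count moved the cause was not tested, except that fits of fewer arrays have fewer degrees of freedom. The pooled spread also changes with the arrays in the fit. For Zn deficiency in shoots, the count of 157 became 95 with quantile normalization, 333 with an added constant of 58, 33 with no filter, 16 with only the 4 arrays compared and 1440 with all 16 arrays in 1 fit. For Zn deficiency in roots, 18 became 33 with all 16 arrays. For mutant shoots, 51 became 19 with no filter, 12 without trend, 17 with only the 4 arrays and 14 with all 16. For mutant roots, 1 became 4 with quantile normalization (2 higher, 2 lower), 3 with median centring (2 and 1), 6 with an added constant of 58, 0 with a filter at the 50th percentile, 4 with only the 4 arrays and 2 with all 16. With an added constant of 1 a single probe set was called there too, lower and not AT3G05170. The Zn by tissue interaction went from 2 to 5 with quantile normalization (3 higher, 2 lower), 4 with a filter at the 50th percentile and 142 with all 16 arrays. The genotype by tissue interaction went from 8 to 3 without trend and 5 with all 16 arrays. The difference between both responses in shoots went from 99 to 225 with an added constant of 58, and with median centring its split was 52 higher and 42 lower, against 68 and 31. The number of called lists went from 3 to 1 with median centring, 1 with an added constant of 58 and 0 without trend. The 6 probe sets shared in shoots and 0 in roots stayed within 1.5 times under every setting with all arrays.

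The labels do not say whether the replicate numbers pair the arrays. Correlations of deviations over 12 pairs of groups lay between -0.115 and 0.18, with 0.165 for control against Zn-deficient shoots. These values show no strong pairing and do not exclude a weak one. With the number as a block, calls went from 157 to 281 in Zn-deficient shoots, from 18 to 23 in Zn-deficient roots, from 1 to 2 in mutant roots and from 99 to 209 for the difference in shoots; the crossed block gave 17 in Zn-deficient roots.

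With 1 array left out, the counts ranged from 17 to 331 (Zn shoots), 12 to 29 (Zn roots), 15 to 179 (mutant shoots), 0 to 6 (mutant roots), 0 to 16 (Zn by tissue), 6 to 28 (genotype by tissue), 11 to 50 (difference in roots), 15 to 776 (difference in shoots), 5 to 12 (shared in shoots), 0 to 0 (shared in roots) and 2 to 4 (lists). In the difference in shoots, the count was 776, 524 and 775 without control shoot replicate 2, Zn-deficient shoot replicate 1 and 2, and 15, 28, 35 and 38 without wild-type replicate 1, 2 and mutant replicate 1, 2; the 12 shared probe sets were those without mutant shoot replicate 2. The 3 called lists were called again in 8 (photosynthesis, Zn shoots), 7 (defensins, Zn roots) and 6 (photosynthesis, mutant roots) of 14 refits; with 1 array left out each held only without Zn-deficient shoot replicate 2, control root replicate 1 and mutant root replicate 2, respectively. Named genes, counted together with the unnamed probe sets called in both shoot comparisons, kept their call in 539 of 654 refits with all arrays. Those unnamed probe sets kept theirs more often than the named genes did, so the share for named genes alone is lower. Called lists kept theirs in 18 of 30 such refits. With 1 array left out, genes and lists both kept their calls less often. Signal limits the dim genes: MTP2 was below background in all groups except Zn-deficient shoots and roots and 1 mutant root array, so its size depends on the added constant. The quantile alternative for HMA2 and HMA4 was not run, since neither has a named probe set.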

Other observations

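All tests in this part were chosen after the results were seen, and the test on mitochondrion-encoded genes replaced 1 on ribosomal RNA.

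Genes encoded in the plastid genome stood out in Zn-deficient shoots, as all 68 tested had negative log2 changes with a median of -0.54 (3 were positive with quantile normalization). Of the 68, 0 passed over all probe sets with limma, and 2 were lower when adjusted over the group alone. An unadjusted limma p under 0.05 was found for 16 of the 68, and for 2849 of all 17059 probe sets. Camera called the group among 33 families (adjusted p = 1.17e-11), but not with an estimated correlation (adjusted p = 0.806). The lower signal was not confined to this group: the median signal of 126 shoot-enriched probe sets, of which 0 are plastid-encoded, was 2030 and 1550 in control and 1020 and 1120 in Zn-deficient shoots. The photosynthesis list had a median log2 change of -0.33, which lay between -0.515 and -0.0905 under other settings or with 1 array left out. Nor was the call of the group confined to Zn-deficient shoots, as in mutant roots camera called it in the other direction (42 positive and 25 negative, median 0.14, and 0.11 and 0.15 with quantile normalization and median centring; adjusted p = 0.0256, and 0.991 with an estimated correlation). The RALF-like peptides had 5 of 7 members negative (median -0.65, and -0.68 and -0.69 with quantile normalization and median centring; camera adjusted p = 0.0426, and 0.806 with an estimated correlation). A range of receptor kinase genes on chromosome 1, picked after its values were seen, had 6 of 7 members positive (median 0.67, and 0.72 and 0.63 with those scalings; camera adjusted p = 0.017, which is not independent of that choice, and 0.806 with an estimated correlation).

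For the plastid genes, between-array scaling is argued against as the whole cause: the median was -0.455 with quantile normalization and -0.583 with median centring. Less priming of RNA without long poly(A) tails is argued against as well, because the 12 mitochondrion-encoded genes tested, whose RNA lacks such tails too, had a median log2 change of 0.151, with 8 positive and 4 negative. The arrays themselves keep the pattern open, since the plastid medians per array were 12.39 and 11.63 in control and 11.73 and 10.69 in Zn-deficient shoots, and so overlapped. Without control replicate 1 and 2 the median was -0.326 and -0.97, without Zn-deficient replicate 1 and 2 it was -0.885 and -0.291, and a dependence on single arrays cannot be told apart from an effect of Zn. A lower level of plastid transcripts under Zn deficiency may be read as a hypothesis only, and whether it is part of the wider fall of shoot-enriched signal was not tested.

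A hypothesis from the direction of the root values was that the genes raised in Zn-deficient roots move down in mutant roots. Of the 15 members of that set that were tested there, 12 were negative and 3 positive, with a median of -0.304. The fry test of limma gave a directional p of 0.212. Camera gave p = 7.8e-06 (lower) at the preset correlation and p = 0.108 with an estimated correlation of 0.312. The tests differ, so the data do not decide it. In mutant shoots 11 of the same 15 were positive, with a median of 1.54, and fry gave a directional p of 0.00166. Of the 6 probe sets called in both shoot comparisons, 4 had an upper 95% bound below 0 in mutant roots, unadjusted for multiple tests, and none of the 6 passed the adjusted threshold with limma.

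An unnamed probe set was below background in the mutant. In mutant shoots its signal was 2.589 ± 0.556 (SD, n = 2) against 182.7 ± 5.7 in the wild type, at least 3.50-fold lower (limma adjusted p = 0.00802). In mutant roots it was 20.06 ± 18.9 against 163.3 ± 3.77, at least 3.12-fold lower, which did not pass (limma adjusted p = 0.293). In Zn-deficient roots it was 1907 ± 85 against 122.9 ± 57.6 in controls, a log2 change of 3.94 that did not pass either (limma adjusted p = 0.271).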
